A study of Rattus norvegicus with 9 samples.

How the data were processed

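RNA was measured in 9 libraries from rat OPC primary cultures, 3 basal, 3 with 1 µM and 3 with 10 µM bavisant, on day 5 in differentiation medium changed every 2 days. The labels name RNeasy extraction, the Illumina Stranded mRNA Prep kit and 75-base paired reads on a NextSeq 500. A protocol text gives 1 mM for the lower dose, while the treatment label and the design text give 1 µM, the dose used here. Per the submitters' processing notes, FastQC, Trimmomatic, DRAGEN and Picard were used with genome build rn6, and the aligner settings, the counter, the strand setting and the annotation release are not given in the sources used here.

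The authors deposited a table of estimated counts per gene (expected counts, about 93% whole numbers), not scaled between libraries, with 1 column per library. The authors also deposited a table of TPM values, scaled by gene length and summing to the same total in each library. Gene names came from these tables, and 399 of 32623 Ensembl IDs had none, holding at most 0.0111% of a library's reads. Where a symbol had several IDs, the lists took the ID with the most reads. The estimated counts were rounded to whole numbers. The depths were 23.9 to 43.1 M reads (M, 1e+06) per library, at which a count of 0 allows up to 3 reads, for counting error only. No genome was used here, so GC content was not analysed here, and gene length was taken as the ratio of counts to TPM.

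Genes were tested in R 4.3.3 with edgeR 4.0.16 by the quasi-likelihood F test on all 9 libraries with 1 coefficient per group, TMM factors and filterByExpr (count minimum 10, total minimum 15), which kept 15321 genes. P-values were adjusted by Benjamini-Hochberg, and an adjusted p under 0.05 was called. The SE of a log2 fold change was its size over the square root of F. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over 33 lists, each with 5 or more tested members. Principal components and ratios per P number used log2 CPM with a prior count of 2. The comparisons, tests, gene lists, naming rule and other settings were fixed before the data were examined.

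The 33 lists covered the lineage (OPC, committed oligodendrocyte, myelin, lineage transcription factors), lipids (cholesterol synthesis, fatty acid synthesis, LXR targets), signalling (histamine system, cAMP-responsive genes, MAPK feedback, Wnt, BMP and Notch targets), cell cycle and p53 targets. They also covered stress (integrated stress response, unfolded protein response, heat shock, NRF2, hypoxia), lysosome, interferon, NF-kB, oxidative phosphorylation, mitochondrially encoded and ribosomal genes, extracellular matrix, axon guidance, and markers of astrocytes, microglia, neurons, vascular, endothelial, Schwann and ependymal cells. Of 891 distinct symbols, 847 were in the file. Genes were named by a rule in 3 parts. The rule took the 10 largest rises and 10 largest falls past the test (from the blocked fit where too few passed) with a mean of at least 2 CPM, a symbol that is no placeholder and 1 direction in all 3 P numbers. It added up to 4 members of each called list with the smallest p and a fixed core of histamine, myelin, precursor, cholesterol, astrocyte and proliferation genes. Other list members are named after their values were seen. Some genes that the rule names are not reported here.

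Whether the P number pairs the libraries was checked from their deviations from group means, by the rule that every same-number pair has a correlation over 0.1. All 9 same-number pairs passed (0.319 to 0.772), and the fit with the P number as an additive block is given beside the results it changes, such as 607 genes against 0 at 10 µM. No pair of libraries in a group agreed within sampling noise (chi-square per degree of freedom 23.8 to 117).

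Other settings for genes, fixed with the main ones, were DESeq2 size factors, library totals and DESeq2 1.42.0. Further ones were limma-trend on log2(TPM + 1) and log2(TPM + 0.1) for genes with TPM of at least 1 in 3 libraries, and limma-trend without that filter. The rest were no count filter, a mean of at least 100 reads, the groups compared alone, robust dispersion, a 1.5-fold minimum, the block, and leaving out each library. For lists they were an estimated correlation, fry, the block, both scalings, the filter at 100 reads and leaving out each library. Combinations of the block with the other settings (except leaving out each library for genes and an estimated correlation for lists, both fixed before), the leaving out of all P11 libraries and the removal of the trend over gene length (loess, span 0.5) were added after seeing the data. Where a group was left with fewer libraries, the fit pooled the spread over all groups.

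The steps were tested on simulated data drawn from the blocked fit with 200 genes changed at 10 µM, and 15202 genes passed the filter. Of genes changed 1.25, 1.5 and 2-fold, the blocked fit recovered 35.8%, 70.1% and 93.9% at 10 µM against basal, with 8 of 141 calls false (5.67%), and 32.8%, 71.6% and 93.9% against 1 µM, with 17 of 149 false (11.4%). The fit without the block recovered 0, 10.4% and 47.0%, and 0, 5.97% and 47.0%, with 0 of 38 and 0 of 35 calls false. At 1 µM, where nothing was changed, the blocked fit made 1 call. A planted list of 25 genes raised 1.3-fold was called by camera with and without the block and with preset and estimated correlations. Of 20 unchanged lists, 0 were called. The simulated genes were drawn independently, so this cannot show how often camera calls lists whose genes move together. In the measured libraries, other splits of the basal and 1 µM libraries called up to 18 lists without the block.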

Results

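Bulk RNA sequencing was done on 9 libraries of rat oligodendrocyte precursor cells (OPCs) in primary culture, kept in differentiation medium and collected on day 5. Of these, 3 were basal, 3 were treated with 1 µM bavisant and 3 with 10 µM bavisant, an antagonist of the histamine H3 receptor. Each group held a library numbered P11, P13 and P14, and the titles do not say what P marks. Nothing in the sources used here states that the numbers are separate cultures or animals, so the p-values may measure technical spread only. The basal libraries held 23.9 (P11), 29.8 (P13) and 33.5 (P14) M estimated reads (M, 1e+06), with a mean of 29.1 ± 4.82 (SD, n = 3). At 1 µM the depths were 39.2, 34.8 and 43.1 M in the same order (39.0 ± 4.13), and at 10 µM they were 39.1, 39.3 and 38.0 M (38.8 ± 0.68). The count table listed 32623 Ensembl IDs, of which 20300 had at least 1 read and 15321 were tested. Mbp was the most abundant gene in 8 of the 9 libraries.

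The P number separated the libraries more than the dose did. The first principal component held 54.7% of the variance of log2 CPM (read counts scaled to a common library total) and set the 3 P11 libraries apart, and the second held 13.4%. After subtracting each group's mean, correlations across genes between libraries that shared a P number were 0.319 to 0.772 in 9 pairs, against -0.708 to 0.193 in 18 pairs from different groups with different numbers, with genes not being independent replicates.

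**Figure D1:**
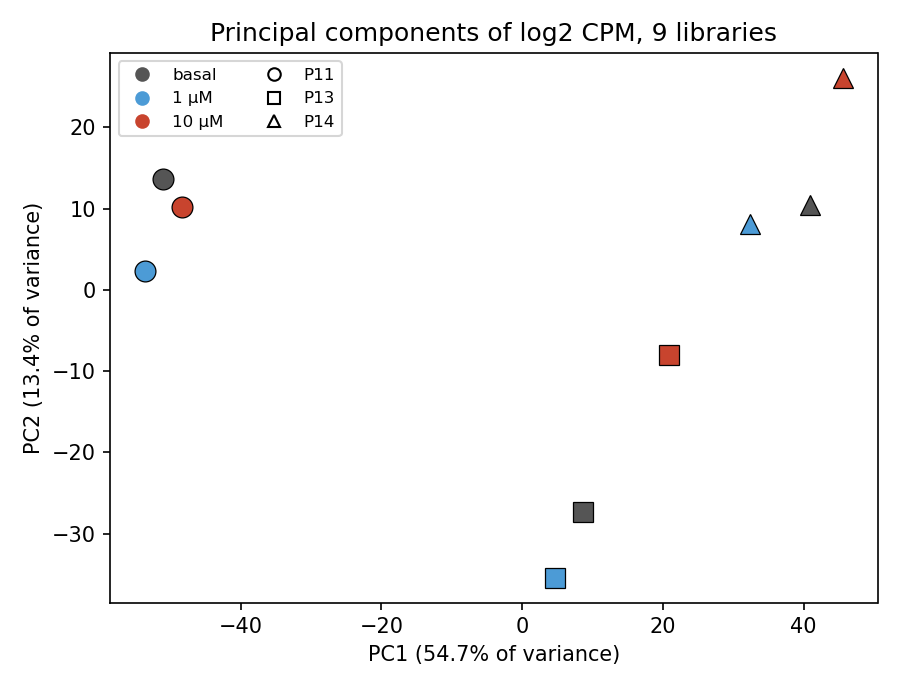
Principal components 1 and 2 of log2 CPM for the 9 libraries, with colour for the dose and marker shape for the P number. The P11 libraries lie on the negative side of component 1 (54.7% of the variance), and component 2 holds 13.4%.

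Among the histamine receptor genes, Hrh1 (ENSRNOG00000007420) had 73 to 184 reads per library and Hrh3 (ENSRNOG00000061153), the target of bavisant, had 9 to 35. Hrh2 (ENSRNOG00000018260) had 1 to 10 reads. Hrh4 (ENSRNOG00000016887) had 0 reads in all 9 libraries, which allows up to 3 reads over all of them, or 0.00935 CPM, for counting error only. Of the genes that make and break down histamine, Hdc (ENSRNOG00000010262) had 0 to 8 reads and Hnmt (ENSRNOG00000005223) 0 to 4, while the histamine-degrading gene Aoc1 (1.20 ± 0.19, adjusted p = 0.0199) rose at 10 µM in the blocked fit. Its call stayed in 4 of 9 runs that leave out 1 library. Aoc1 was far lower in P11 than in P13 and P14 (log2 fold change -4.40 ± 0.22). At 10 µM neither Hrh1 (-0.23 ± 0.21, adjusted p = 0.559) nor Hrh3 (-0.19 ± 0.37, adjusted p = 0.793) passed the test. The histamine system list did not pass either, at a median log2 fold change of -0.12 (adjusted p = 0.939), whose mean of 0.11 and test direction were positive.

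The comparison of 10 µM bavisant with basal cultures asks what the higher dose does to OPCs while they differentiate. Without the P number in the edgeR fit, 0 genes passed the test and the lowest adjusted p was 0.462. In that fit 808 genes had an unadjusted p under 0.05, against 766 for uniform p-values. Its spread held the differences between P numbers (common dispersion 0.0675, against 0.00696 with the block). These counts therefore cannot show that the dose had no effect. DESeq2 called 59 genes, and limma on TPM called 0. With the P number as a replicate block, 607 of 15321 genes passed, 202 higher and 405 lower (66.7% lower). Their median size was 1.35-fold, with the same direction in all 3 P numbers. In this fit 3436 genes had an unadjusted p under 0.05. Under scaling by library totals 84.3% of the blocked calls were lower, and by limma on TPM 82.9%. Of the 59 DESeq2 genes, 55 were among the 607. Gene values for this comparison come from the blocked fit, as log2 fold changes ± SE with n = 3 libraries per group, and CPM are means ± SD, with 10 µM first. Of 53 genes taken by the naming rule and called in that fit, 0 stayed called in all 9 runs that leave out 1 library (median 4, range 1 to 7 runs). All 53 kept their direction, which was nearly fixed in advance, since all 607 calls had 1 direction in all 3 P numbers.

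Cholesterol synthesis and uptake genes rose as a group, with a median log2 fold change of 0.40 over 25 tested genes, adjusted p = 2.66e-42, and adjusted p = 0.0602 with an estimated correlation. These genes make the sterol that is the main lipid of myelin membranes. The list medians were 0.40, 0.46 and 0.33 in P11, P13 and P14. With the block, 19 of 25 genes rose over all genes and 24 adjusted over the list alone, and without it 0 and 20 did. Idi1 (ENSRNOG00000016690, 327 ± 20.5 against 219 ± 22.1 CPM, log2 fold change 0.58 ± 0.07, adjusted p = 0.0129) rose. The feedback sensor Insig1 (ENSRNOG00000006859, 443 ± 51.1 against 298 ± 12.4 CPM, log2 fold change 0.56 ± 0.07, adjusted p = 0.0129) rose as well, and so did Mvk (0.48 ± 0.05, adjusted p = 0.0101), which acts early in the pathway. Cyp51 (0.47 ± 0.06, adjusted p = 0.0164) and Nsdhl (0.34 ± 0.05, adjusted p = 0.0164), which act late in the pathway, also rose. The epoxidase Sqle (0.34 ± 0.06, adjusted p = 0.0273) rose as well.

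Genes for cholesterol efflux moved the other way. The list of LXR targets fell, with a median log2 fold change of -0.18 over 11 tested genes, adjusted p = 0.0119, and adjusted p = 0.460 with an estimated correlation. LXR is the nuclear receptor that senses oxidised sterols and drives the export of cholesterol. The exporter Abca1 (ENSRNOG00000018126, 192 ± 78.4 against 363 ± 177 CPM, log2 fold change -0.90 ± 0.11, adjusted p = 0.0120) fell. So did Abcg1 (-0.46 ± 0.05, adjusted p = 0.0101) and Srebf1 (-0.62 ± 0.12, adjusted p = 0.0315), which were the 3 genes called in the list. Adjusted over the list alone, 5 fell with the block, the others being Mylip (-0.26) and Smpdl3a (-0.32), and 1 (Abcg1) without it. Without the block the call ended without the basal P11 (adjusted p = 0.0582), basal P13 (0.0967) or 10 µM P14 library (0.259), while in the blocked fit no left-out library ended it (adjusted p = 2.63e-04 with all 9). The list of fatty acid and complex lipid synthesis did not pass, with a median of -0.01 (adjusted p = 0.391) and a positive test direction, although Gal3st1 (0.33), Elovl1 (0.40), Acss2 (0.36) and Cers2 (0.29) rose in it and Srebf1 (-0.62) fell.

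Myelin and mature oligodendrocyte genes rose as a list, with a median log2 fold change of 0.26 over 39 tested genes, adjusted p = 4.84e-07, and adjusted p = 0.630 with an estimated correlation. Mbp, a main protein of the myelin sheath (ENSRNOG00000016516, 31530.5 ± 1441 against 21716 ± 1739.9 CPM, log2 fold change 0.54 ± 0.07, adjusted p = 0.0125) rose. Mag (ENSRNOG00000021023, 2834 ± 656 against 1947 ± 247 CPM, log2 fold change 0.53 ± 0.08, adjusted p = 0.0177) rose too, as did Cnp (0.34 ± 0.05, adjusted p = 0.0169) and Mobp (0.66 ± 0.11, adjusted p = 0.0242). The sulfatide enzyme Gal3st1 (0.33 ± 0.05, adjusted p = 0.0164) and Aspa (0.38 ± 0.05, adjusted p = 0.0164) rose too. Over all genes 13 of 39 members rose and 0 fell, and adjusted over the list alone 23 rose and 2 fell, Cntn2 (-0.43) and Car2 (-0.26). Mog (0.34 ± 0.10, adjusted p = 0.0890) and Myrf (0.13 ± 0.05, adjusted p = 0.193) did not pass. Without the block, leaving out the 10 µM P11 library ended the list call (adjusted p = 0.104), and in the blocked fit no left-out library did (adjusted p = 9.39e-16 with all 9).

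**Figure D2:**
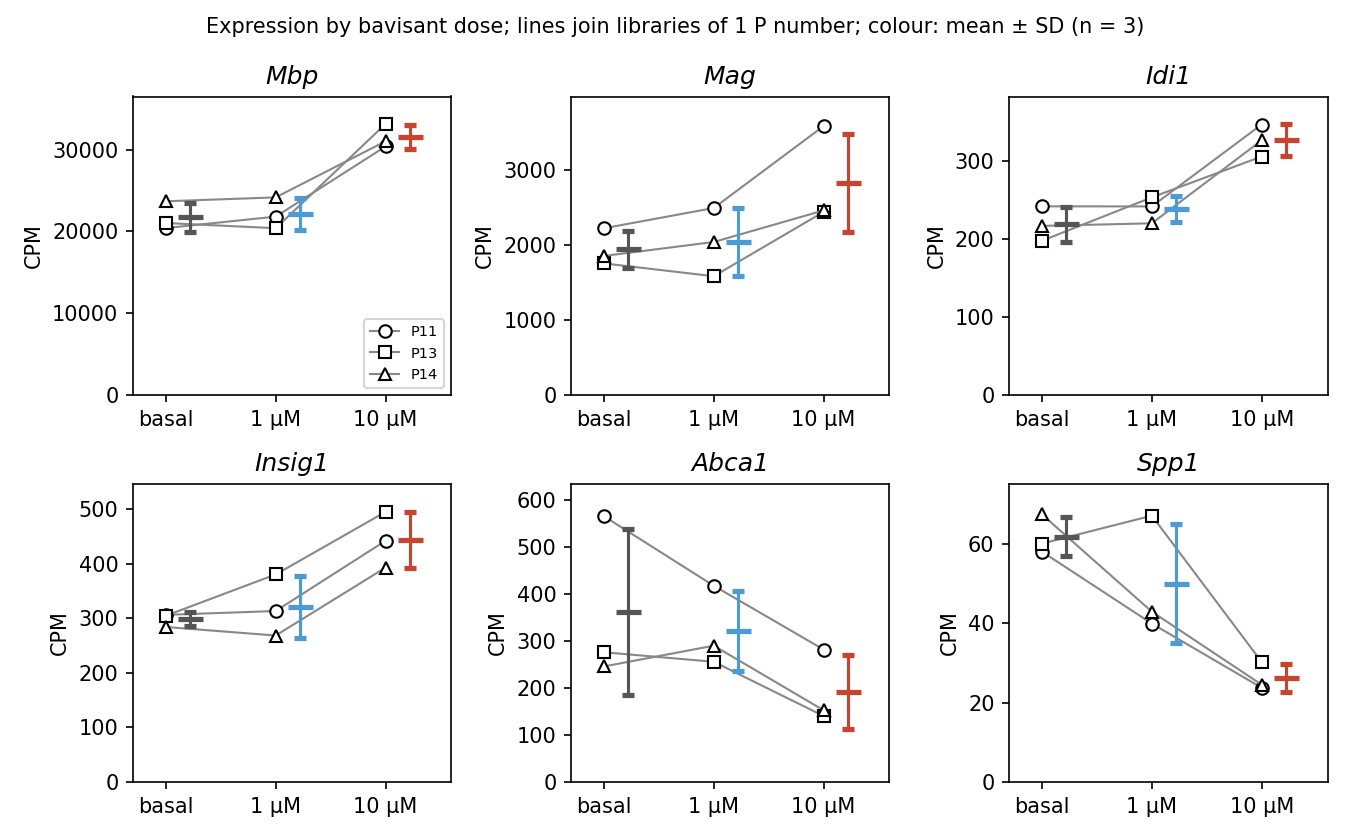
CPM of 6 genes in each of the 9 libraries by dose (µM), with lines joining libraries of 1 P number and coloured bars for the group mean ± SD (n = 3). Mbp, Mag, Idi1 and Insig1 lay higher and Abca1 and Spp1 lower at 10 µM than in the basal library of the same number, with log2 fold changes from 0.58 (Idi1) to -1.26 (Spp1).

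The committed and newly formed oligodendrocyte list rose (median log2 fold change of 0.25 over 18 tested genes, adjusted p = 0.00567, and adjusted p = 0.222 with an estimated correlation). In it Sirt2 (0.30 ± 0.06, adjusted p = 0.0401), Kif19 (0.53 ± 0.11, adjusted p = 0.0367) and Rras2 (0.48 ± 0.05, adjusted p = 0.0114) rose, and adjusted over the list alone 7 rose and 1 fell, Prom1 (-0.58). The oligodendrocyte lineage transcription factors rose (median log2 fold change of 0.11 over 22 tested genes, adjusted p = 0.00771, and adjusted p = 0.266 with an estimated correlation). In them Olig1 (0.34 ± 0.05, adjusted p = 0.0217) and Olig2 (0.29 ± 0.06, adjusted p = 0.0378) were the called members, with 5 higher and 1 lower, Id4 (-0.34), adjusted over the list alone. That call ended without the 10 µM P11 library (adjusted p = 0.0524), and with the block it was 0.0160. Sox10 (0.30 ± 0.07, adjusted p = 0.0502) did not pass. The OPC list, which marks the precursor stage, did not pass, with a median of 0.02 (adjusted p = 0.448), and neither did Pdgfra (0.18 ± 0.05, adjusted p = 0.0926) or Cspg4 (0.22 ± 0.05, adjusted p = 0.0676). The cell cycle list did not pass either, with a median of 0.10 (adjusted p = 0.712), nor did the proliferation marker Mki67 (-0.14 ± 0.15, adjusted p = 0.601). In the fit without the block the list was called higher without the 10 µM P11 library (adjusted p = 2.15e-07) and lower without the 10 µM P14 library (0.0235).

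Genes of energy supply and translation rose by small amounts. Nuclear oxidative phosphorylation genes had a median log2 fold change of 0.11 over 59 tested genes, adjusted p = 9.96e-09, and adjusted p = 0.630 with an estimated correlation. Of these, 0 of 59 were called in the blocked fit and 0 adjusted over the list alone. Ribosomal protein genes had a median log2 fold change of 0.10 over 71 tested genes, adjusted p = 4.84e-07, and adjusted p = 0.641 with an estimated correlation. Here Rpl36 (0.38 ± 0.07, adjusted p = 0.0338) was the only called member, with 0 adjusted over the list alone. Mitochondrially encoded genes had a median log2 fold change of 0.15 over 13 tested genes, adjusted p = 0.00822, and adjusted p = 0.630 with an estimated correlation, and their medians were -0.23, 0.40 and 0.23 in P11, P13 and P14. That call ended without the basal P13 (adjusted p = 0.414) or 10 µM P14 library (0.289), and with the block it ended without the basal P13 (0.0734), basal P14 (0.250), 10 µM P13 (0.765) or 10 µM P14 library (0.0552).

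Inflammatory genes fell. The NF-kB and cytokine list had a median log2 fold change of -0.47 over 26 tested genes, adjusted p = 6.23e-05, and adjusted p = 0.460 with an estimated correlation, and its call held with each of the 9 libraries left out. The cytokine Tnf (ENSRNOG00000000837, 2.31 ± 1.09 against 4.73 ± 1.60 CPM, log2 fold change -1.07 ± 0.16, adjusted p = 0.0177) fell. Lower too were Nfkbiz (-0.48 ± 0.10, adjusted p = 0.0438), Nfkbia (-0.31 ± 0.06, adjusted p = 0.0328), Lcn2 (-0.67 ± 0.09, adjusted p = 0.0164) and Vcam1 (-0.50 ± 0.09, adjusted p = 0.0263), with Tnf the 5 called members, and 11 were lower adjusted over the list alone. Microglia and macrophage markers also fell (median log2 fold change of -0.17 over 31 tested genes, adjusted p = 6.08e-04, and adjusted p = 0.630 with an estimated correlation). The list medians were -0.0046, -0.29 and -0.25 in P11, P13 and P14, so the list hardly moved in P11. The mannose receptor Mrc1 (-0.62 ± 0.09, adjusted p = 0.0164), the integrin Itgam (-0.47 ± 0.06, adjusted p = 0.0139) and Cd68 (-0.26 ± 0.05, adjusted p = 0.0341) fell. Fcgr2b (-0.41) and Ly86 (-0.52) completed the 5 called members, and 9 fell adjusted over the list alone. The complement genes C1qa (-0.07 ± 0.06, adjusted p = 0.519) and C1qb (-0.11 ± 0.08, adjusted p = 0.465) and the receptor gene Csf1r (-0.14 ± 0.09, adjusted p = 0.372), picked after their values were seen, did not pass. The microglia call ended without the basal P13 (adjusted p = 0.170) or 10 µM P14 library (0.0551), and in the blocked fit no left-out library ended it (adjusted p = 1.14e-05 with all 9). The interferon list did not pass, with a median of -0.12 (adjusted p = 0.215).

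Extracellular matrix genes, astrocyte markers and axon guidance genes fell. The extracellular matrix list had a median log2 fold change of -0.35 over 34 tested genes, adjusted p = 0.00771, and adjusted p = 0.697 with an estimated correlation. In it 5 members were called, Mmp2 (-0.64 ± 0.05, adjusted p = 0.0101), Sparc (-0.35 ± 0.05, adjusted p = 0.0164), Col5a2 (-0.51), Col6a2 (-0.59) and Bgn (-0.38), with 23 lower adjusted over the list alone. Its call ended without the basal P11 (adjusted p = 0.920, in the other direction) or 10 µM P14 library (0.772), and with the block (adjusted p = 9.39e-16) no left-out library ended it. Astrocyte markers fell (median log2 fold change of -0.26 over 27 tested genes, adjusted p = 2.53e-04, and adjusted p = 0.475 with an estimated correlation). The glutamate transporters Slc1a2 (-0.65 ± 0.14, adjusted p = 0.0460) and Slc1a3 (-0.40 ± 0.09, adjusted p = 0.0479) were called lower, with Acsbg1 (-0.52) and Slc4a4 (-0.66), and 9 fell adjusted over the list alone. Aqp4 (-0.46 ± 0.12, adjusted p = 0.0694) and Gfap (-0.20 ± 0.05, adjusted p = 0.0650) did not pass. Axon guidance, adhesion and synapse genes fell (median log2 fold change of -0.16 over 33 tested genes, adjusted p = 0.0145, and adjusted p = 0.630 with an estimated correlation). The called members were 7 lower, such as Robo2 (-0.45 ± 0.06, adjusted p = 0.0164) and Sema3c (-0.41 ± 0.09, adjusted p = 0.0493), and 2 higher, Sema4d (0.35 ± 0.06, adjusted p = 0.0201) and Lingo1 (0.24). There were 12 lower and 2 higher adjusted over the list alone. That call ended without the basal P14 (adjusted p = 0.231), 10 µM P11 (0.174) or 10 µM P13 library (0.113), and with the block (adjusted p = 4.49e-05) no left-out library ended it.

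Targets of Wnt, BMP and Notch fell (median log2 fold change of -0.16 over 20 tested genes, adjusted p = 0.0425, and adjusted p = 0.475 with an estimated correlation), with 0 of 20 called. That call ended without the basal P11 (adjusted p = 0.196), basal P14 (0.146), 10 µM P11 (0.151) or 10 µM P14 library (0.0868), under library totals (0.0634) and under the filter at a mean of 100 reads (0.0511). With the block (adjusted p = 0.0478) it ended without the basal P11 (0.205), basal P14 (0.0600), 1 µM P11 (0.0546), 10 µM P11 (0.263) or 10 µM P14 library (0.197).

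A further 4 lists fell only in the blocked fit. Neuron markers had a median log2 fold change of -0.16 (adjusted p = 1.02e-04, adjusted p = 0.155 with an estimated correlation; without the block 0.0869). The called neuron genes were Gad1 (-0.60), Gad2 (-0.72), Stmn2 (-0.36) and Slc32a1 (-0.33), all lower, with 1 higher and 5 lower adjusted over the list alone. Vascular mural and fibroblast markers had -0.30 (adjusted p = 0.00622, adjusted p = 0.318 with an estimated correlation; without the block 0.311). The only called vascular gene, Mylk (0.59 ± 0.08, adjusted p = 0.0164), was higher, with 1 higher and 7 lower adjusted over the list alone. The NRF2 oxidative response had -0.09 (adjusted p = 0.0306, adjusted p = 0.349 with an estimated correlation; without the block 0.0869). The called NRF2 genes were Slc7a11 (-0.91), Hmox1 (-0.46) and Mt2A (-0.67), lower, and Ftl1 (0.41), higher, with 1 higher and 5 lower adjusted over the list alone. Endothelial markers had -0.47 (adjusted p = 0.0414, adjusted p = 0.309 with an estimated correlation; without the block 0.201), with Eng (-0.53) lower and 5 lower adjusted over the list alone. The NRF2 call ended without the basal P14 (adjusted p = 0.0971), 1 µM P11 (0.0520), 10 µM P11 (0.158) or 10 µM P14 library (0.259). The endothelial call ended without the basal P14 (0.0585), 1 µM P11 (0.0546), 10 µM P11 (0.108) or 10 µM P14 library (0.0974).

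The largest falls among named genes were in the matrix protease Mmp9 (-1.75 ± 0.24, adjusted p = 0.0164) and the osteopontin gene Spp1 (ENSRNOG00000043451, 26.2 ± 3.56 against 61.9 ± 4.94 CPM, log2 fold change -1.26 ± 0.14, adjusted p = 0.0114). Next came Cd93 (-1.22), Itgb4 (-1.22), Grin2b (-1.12), Dok2 (-1.10), Tnf, Angptl4 (-1.01), Lrat (-1.01) and Nhs (-0.99). The largest rises were in Aoc1 (1.20 ± 0.19, adjusted p = 0.0199), which codes for the histamine-degrading diamine oxidase (ENSRNOG00000008575). Next came Hist2h2aa3 (0.96), Cxcl13 (0.88), Sgk2 (0.80), Grm7 (0.67), Mobp, Eif4e3 (0.61), Dapk2 (0.61) and Mylk. The sphingosine phosphate receptor gene S1pr5 (ENSRNOG00000020901, 86.7 ± 9.75 against 57.3 ± 0.619 CPM, log2 fold change 0.59 ± 0.08, adjusted p = 0.0164) also rose. Of these, Cxcl13, Dapk2, Angptl4 and Lrat stayed called in 1 of 9 left-out runs.

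The remaining lists passed in neither fit at 10 µM. By median log2 fold change without the block the signalling lists were cAMP-responsive and immediate early genes -0.05 (adjusted p = 0.0980) and MAPK feedback targets -0.09 (adjusted p = 0.381). The stress lists were the integrated stress response -0.12 (adjusted p = 0.636), the unfolded protein response -0.01 (adjusted p = 0.476), heat shock -0.02 (adjusted p = 0.939) and hypoxia and glycolysis -0.02 (adjusted p = 0.460). The others were lysosome and autophagy 0.02 (adjusted p = 0.476), p53 targets and apoptosis -0.08 (adjusted p = 0.138), Schwann cell markers -0.21 (adjusted p = 0.658) and ependymal and cilia markers -0.37 (adjusted p = 0.137), beside those already given. The test direction was up for the unfolded protein response and Schwann cell lists, whose medians were negative, and the lysosome list had a mean of -0.00. Without the basal P11 library the integrated stress response was called higher in the fit without the block (adjusted p = 0.0203). Called members in these lists included Cdkn1a (-0.46) and Fas (-0.58) among p53 targets, Ctsl (0.45), Ctsb (-0.23) and Gpnmb (-0.54) among lysosome genes, and Pmp2 (0.42) among Schwann cell genes.

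Of 33 lists, 14 passed without the block (7 up, 7 down) and 18 with it (7 up, 11 down), while 0 did with an estimated correlation in either fit (lowest adjusted p = 0.0602 and 0.135). The test fry, which asks whether a list's genes move 1 way on balance, called 2 without the block, cholesterol and the committed oligodendrocyte list, and 6 with it. The 607 blocked calls changed when single libraries were left out, falling to 0 without the basal P11, 1 (Spp1) without the basal P13 and 57 without the basal P14 library. They fell to 260 without the 1 µM P11, 261 without the 1 µM P14, 158 without the 10 µM P13 and 64 without the 10 µM P14 library. The calls numbered 581 without the 1 µM P13 and 529 without the 10 µM P11 library. Compared without the 1 µM libraries, the blocked fit called 0 genes. Without the basal P11, P13 and P14 libraries, 2689, 2268 and 2837 genes had an unadjusted p under 0.05. Runs with fewer libraries have less power, so the lost calls do not by themselves show dependence on a particular library.

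**Figure D3:**
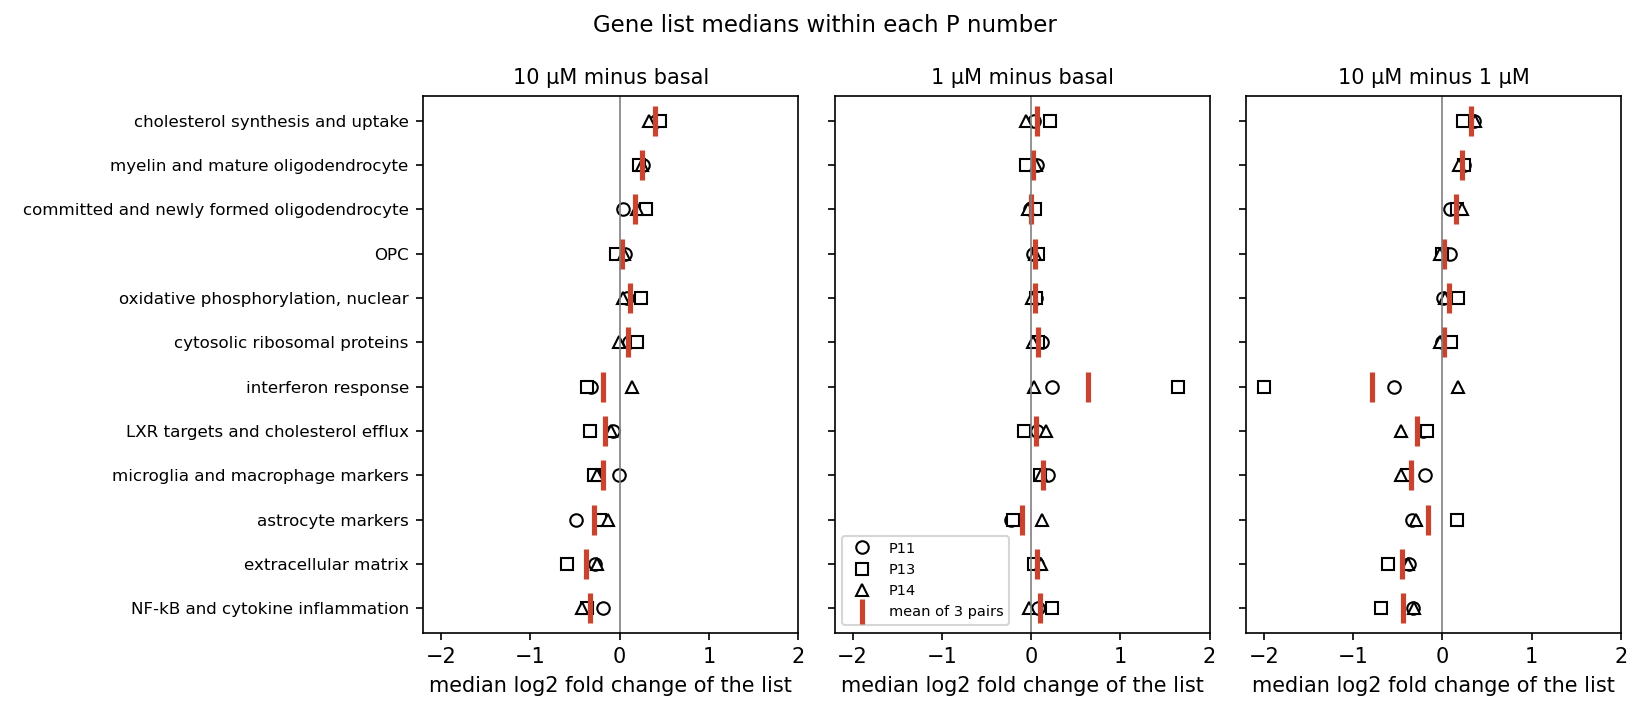
Median log2 ratio of 12 gene lists for each P number (open markers) in the 3 comparisons, with a red bar for the mean over P11, P13 and P14. Cholesterol synthesis lay above 0 at 10 µM against basal in all 3 numbers (0.40, 0.46 and 0.33), and interferon at 1 µM stood at 0.23, 1.65 and 0.03.

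The comparison of 1 µM bavisant with basal asks whether the lower dose changes the same cultures. edgeR called 0 genes without the block, with a lowest adjusted p of 0.99988. In that fit 81 genes had an unadjusted p under 0.05, against 766 for uniform p-values. With the block edgeR called 0 (582 unadjusted), or 2 (Gdf1 and AABR07068162.1) when the 10 µM P11 library was left out. DESeq2 called 5 genes, named after their values were seen, and limma on TPM called 0. Ifit3 (5.74) and Rn7sl1 (20.1) were higher, and Hspa1b (-1.36), AABR07068162.1 (-8.50) and Gdf1 (-24.3) lower. Ifit3 had 912 reads in the 1 µM P13 library, against 40 and 10 in P11 and P14. Rn7sl1 had 117 reads in that library, and 0 in the other 1 µM and the basal libraries. Gdf1 had 434 reads in the basal P11 library, and 0 in the other basal and the 1 µM libraries. AABR07068162.1 had 0 reads in every 1 µM library. With the block DESeq2 called 11. None of the myelin or cholesterol genes named at 10 µM passed, such as Mbp (0.03 ± 0.07, adjusted p = 1.00), Mag (0.05 ± 0.08, adjusted p = 1.00) and Insig1 (0.09 ± 0.07, adjusted p = 1.00). The receptor genes Hrh3 (0.10 ± 0.36, adjusted p = 1.00) and Hrh1 (-0.17 ± 0.21, adjusted p = 1.00) did not pass either.

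Interferon response genes were the list with the largest change, with a median log2 fold change of 0.81 over 36 tested genes, adjusted p = 1.31e-51, and adjusted p = 0.525 with an estimated correlation. These genes are switched on by interferon signalling. The medians were 0.23, 1.65 and 0.03 in P11, P13 and P14, so that the list rose mainly in 1 library, and with the block its adjusted p was 1.79e-27. Without the 1 µM P13 library it was 1.15e-06, and with the block 8.67e-04. Ifit3 (ENSRNOG00000022839) stood at 8.87 ± 14.3 against 0.167 ± 0.0816 CPM, with log2 ratios of 1.79, 7.37 and 0.48 in P11, P13 and P14. Isg15 (ENSRNOG00000021802) stood at 18.1 ± 26.0 against 2.07 ± 0.726 CPM, with 0.59, 4.82 and 0.16 in P11, P13 and P14. Neither passed the test over all genes. All 36 interferon genes were highest in the 1 µM P13 library, with Ifit3 at 25.4 CPM (24.7 times the next library), Isg15 at 48.1 (10.9 times) and Irf7 at 43.2 (9.16 times), and RT1-CE1 at 1.00 times.

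**Figure D4:**
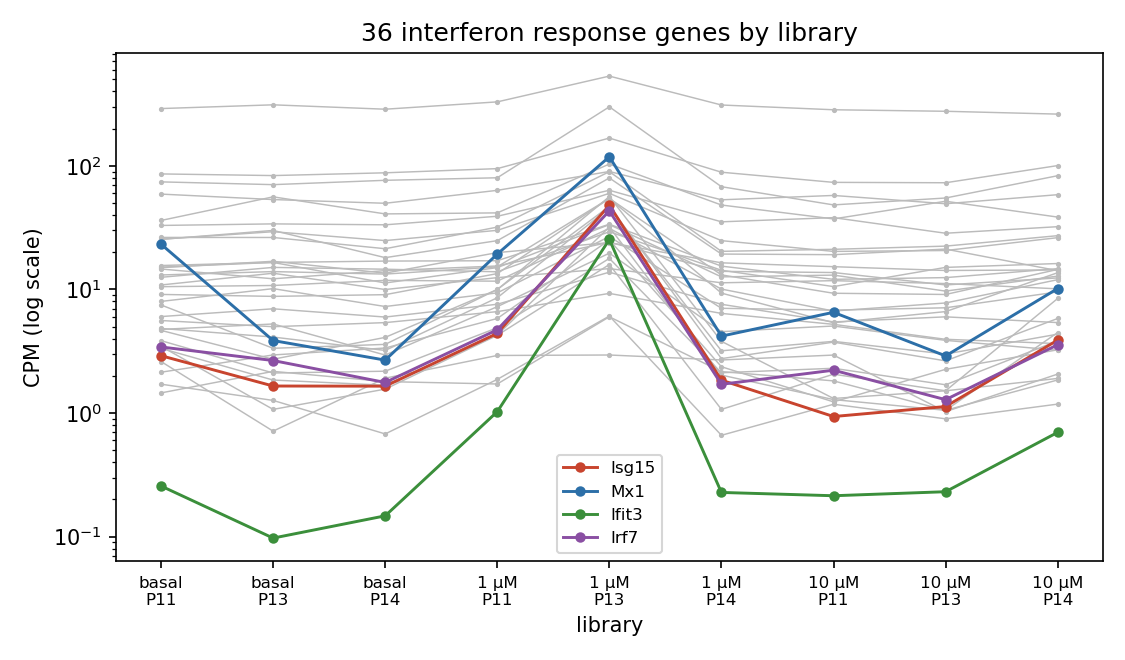
CPM (log axis) of 36 interferon genes, 1 line each, in the 9 libraries by group and P number, with Isg15, Mx1, Ifit3 and Irf7 in colour. The 1 µM P13 library is the highest, with Ifit3 at 25.4 and Isg15 at 48.1 CPM.

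At 1 µM 8 of 33 lists passed without the block (7 up, 1 down) and 15 with it (11 up, 4 down), and 0 did with an estimated correlation in either fit (lowest adjusted p = 0.525 and 0.226). Beside interferon, ribosomal proteins rose (median log2 fold change of 0.08 over 71 tested genes, adjusted p = 4.10e-09, and adjusted p = 0.865 with an estimated correlation). Cholesterol synthesis rose (median log2 fold change of 0.08 over 25 tested genes, adjusted p = 2.01e-06, and adjusted p = 0.709 with an estimated correlation). Microglia markers rose (median log2 fold change of 0.13 over 31 tested genes, adjusted p = 1.37e-06, and adjusted p = 0.709 with an estimated correlation). NF-kB genes rose (median log2 fold change of 0.14 over 26 tested genes, adjusted p = 0.00261, and adjusted p = 0.709 with an estimated correlation). Oxidative phosphorylation rose (median log2 fold change of 0.04 over 59 tested genes, adjusted p = 0.00261, and adjusted p = 0.925 with an estimated correlation). Targets of p53 rose (median log2 fold change of 0.04 over 20 tested genes, adjusted p = 0.0433, and adjusted p = 0.709 with an estimated correlation), a call ending under the filter at a mean of 100 reads (0.0692). Mitochondrially encoded genes fell (median log2 fold change of -0.20 over 13 tested genes, adjusted p = 2.04e-09, and adjusted p = 0.709 with an estimated correlation). In these lists 0 members were called over all genes, in either fit. There are 10 ways to split the basal and 1 µM libraries into groups of equal size, the real one included. Without the block, 8 of them gave at least as many lists (highest other 18). With it, 2 of the 4 that part every pair did (highest other 15). The number of list calls thus does not set the dose apart from other groupings.

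These calls depended on single libraries, and 14 lists passed without the basal P11 library and 15 without the 1 µM P14 library. Without the 1 µM P13 library, cholesterol (0.0869), NF-kB (0.471, in the other direction), mitochondrially encoded (0.166), p53 (0.133) and microglia (0.173) lists no longer passed. Without the basal P13 library, cholesterol (0.103), oxidative phosphorylation (0.311) and p53 (0.566) did not. Without the basal P11 library, NF-kB (0.130), mitochondrially encoded (0.0605) and microglia (0.651) did not. Without the basal P14 library, NF-kB (0.0805), oxidative phosphorylation (0.999, in the other direction), ribosomal proteins (0.585) and p53 (0.253) did not. Without the 1 µM P11 library, oxidative phosphorylation (0.111, in the other direction), ribosomal proteins (0.630) and p53 (0.576) did not. All these values are adjusted p from the fit without the block. With the block, the cholesterol call ended without the basal P13 (0.128) or 1 µM P13 library (0.480), NF-kB without the 1 µM P13 (0.604) and mitochondrially encoded genes without the basal P11 (0.0666). Oxidative phosphorylation ended without the basal P13 (0.725) or 1 µM P11 (0.209), and p53 without the basal P13 (0.363) or 1 µM P13 (0.851).

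With the block, a further 7 lists passed at 1 µM, given by median log2 fold change. Upward were the integrated stress response 0.04 (adjusted p = 3.66e-04, adjusted p = 0.506 with an estimated correlation) and the unfolded protein response 0.03 (adjusted p = 0.0466, adjusted p = 0.611 with an estimated correlation). So were extracellular matrix 0.08 (adjusted p = 2.54e-04, adjusted p = 0.516 with an estimated correlation) and vascular and fibroblast markers 0.11 (adjusted p = 0.0118, adjusted p = 0.506 with an estimated correlation). Axon guidance -0.05 (adjusted p = 0.00116, adjusted p = 0.565 with an estimated correlation) and astrocyte markers -0.09 (adjusted p = 0.00347, adjusted p = 0.671 with an estimated correlation) passed downward. Neuron markers -0.09 (adjusted p = 4.82e-07, adjusted p = 0.226 with an estimated correlation) did too, with Stmn2, Gad1 and Slc32a1 lower adjusted over the neuron list alone. No left-out library ended the neuron call. The stress response call ended without the basal P13 (adjusted p = 0.496) or 1 µM P13 library (0.111), the matrix call without the basal P14 (0.142) or 1 µM P13 (0.0824), and the axon call without the 1 µM P11 (0.548). The astrocyte call ended without the basal P11 (0.937), basal P13 (0.0759) or 1 µM P13 library (0.896, in the other direction), and the vascular call without the basal P14 (0.376) or 1 µM P14 (0.991). The unfolded protein response call ended without the basal P13 (0.363), basal P14 (0.273), 1 µM P13 (0.583), 10 µM P11 (0.0644) or 10 µM P14 library (0.0663). The matrix list, in the fit without the block, was called lower without the basal P14 (adjusted p = 2.88e-04) or 1 µM P11 library (0.00481) and higher without the basal P11 (4.71e-05) or 1 µM P14 library (1.62e-05). The unfolded protein response was called lower without the 1 µM P11 (0.0125) and higher without the basal P11 (3.48e-06) or 1 µM P14 library (0.00515). Under library totals without the block, astrocyte (0.0348) and neuron markers (0.0349) passed downward.

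The remaining lists did not pass at 1 µM in either fit. By median log2 fold change without the block, the lineage lists were OPC 0.04 (adjusted p = 0.410), committed oligodendrocyte -0.00 (adjusted p = 0.864), myelin 0.04 (adjusted p = 0.564), lineage transcription factors 0.03 (adjusted p = 0.222) and cell cycle 0.07 (adjusted p = 0.324). The metabolic and signalling lists were fatty acid synthesis -0.01 (adjusted p = 0.438), LXR targets 0.03 (adjusted p = 0.182), histamine system -0.01 (adjusted p = 0.729), cAMP-responsive genes 0.03 (adjusted p = 0.864), MAPK feedback -0.02 (adjusted p = 0.864), Wnt, BMP and Notch targets 0.01 (adjusted p = 0.864) and hypoxia 0.03 (adjusted p = 0.314). The others were heat shock 0.03 (adjusted p = 0.831), NRF2 response 0.04 (adjusted p = 0.410), lysosome 0.00 (adjusted p = 0.729), endothelial 0.02 (adjusted p = 0.698), Schwann cell 0.03 (adjusted p = 0.865) and ependymal markers -0.04 (adjusted p = 0.565). The test direction was down for heat shock and Schwann cell lists and up for the committed oligodendrocyte list, against the sign of their medians, and the cAMP list had a mean of -0.01. With single libraries left out, some of these lists were called in both directions. In the fit without the block, the myelin list was called lower without the 1 µM P11 library (adjusted p = 1.70e-04) and higher without the basal P11 (1.72e-04) or 1 µM P13 library (8.53e-05). The cAMP list was called lower without the 1 µM P11 (0.00481) and higher without the basal P11 library (0.00166). With the block, the cell cycle list was called lower without the basal P13 (adjusted p = 0.00212) and higher without the basal P11 (1.43e-12), 1 µM P14 (8.23e-05) or 10 µM P11 library (0.0101).

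The comparison of 10 µM with 1 µM bavisant asks which changes separate the doses. edgeR called 0 genes without the block (lowest adjusted p = 0.867). The genes with an unadjusted p under 0.05 were 717 without the block and 3246 with it. DESeq2 called 58, of which 55 were among the blocked calls, and limma on TPM called 0. With the block 659 genes passed, 200 higher and 459 lower (69.7% lower; 87.4% under library totals and 84.5% by limma on TPM), with a median size of 1.36-fold. The vesicle fusion gene Vamp1 (0.66 ± 0.06, adjusted p = 0.0123) rose. So did Aoc1 (0.97), Grm7 (0.72), Sgk2 (0.69), Nfe2l3 (0.67), S1pr5 (0.55), Dapk2 (0.55) and Kif17 (0.53). The heat shock gene Hspa1b was higher at 10 µM than at 1 µM (1.18 ± 0.18, adjusted p = 0.0206). DESeq2 had called Hspa1b lower at 1 µM than in basal cultures (-1.36). Its difference between the doses therefore does not show a rise over basal at 10 µM. The largest falls were in Esm1 (-1.58), the chemokine genes Ccl7 (-1.31) and Ccl2 (-1.20), S100a6 (-1.30), Mmp9 (-1.26), Gbp6 (-1.09), Aebp1 (-1.08), Plac8 (-1.05), Ms4a6e (-1.02) and Cd93 (-1.02). Over the 9 left-out runs, Ccl7 and Dapk2 stayed called in 0, Ccl2, Plac8 and Cd93 in 1 and Esm1 in 2. Of 58 genes taken by the naming rule and called here, 0 stayed called in all 9 runs (median 4, range 0 to 6) and 8 in no run. All 58 kept their direction, which was again nearly fixed in advance, since all 659 calls had 1 direction in all 3 P numbers.

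Myelin genes rose (median log2 fold change of 0.25 over 39 tested genes, adjusted p = 1.81e-06, and adjusted p = 0.480 with an estimated correlation). Of them 14 were called higher and 1 lower, Tf (-0.53 ± 0.12, adjusted p = 0.0455), and 23 higher and 2 lower adjusted over the list alone. Mbp (ENSRNOG00000016516, 31530.5 ± 1441 against 22130.3 ± 1906 CPM, log2 fold change 0.51 ± 0.07, adjusted p = 0.0141) rose. So did Mag (0.47 ± 0.08, adjusted p = 0.0228), Cnp (0.30), Mobp (0.56) and Myrf (0.24 ± 0.05, adjusted p = 0.0462). Mog (0.28 ± 0.10, adjusted p = 0.144) did not pass. The myelin call ended without the 10 µM P11 library (adjusted p = 0.229), and with the block it was 6.85e-15. The committed oligodendrocyte list rose (median log2 fold change of 0.16 over 18 tested genes, adjusted p = 0.00551, and adjusted p = 0.170 with an estimated correlation). Its called members were Rras2 (0.47 ± 0.05, adjusted p = 0.0141) and Sirt2 (0.30 ± 0.06, adjusted p = 0.0374), and 7 passed adjusted over the list alone. Cholesterol synthesis rose (median log2 fold change of 0.32 over 25 tested genes, adjusted p = 3.04e-30, and adjusted p = 0.136 with an estimated correlation). In the blocked fit 16 of 25 were called, and 23 adjusted over the list alone (16 without the block). Among them were Sc5d (0.37 ± 0.05, adjusted p = 0.0141), Insig1 (0.47 ± 0.07, adjusted p = 0.0182) and Cyp51 (0.40 ± 0.06, adjusted p = 0.0218). LXR targets fell (median log2 fold change of -0.17 over 11 tested genes, adjusted p = 2.50e-04, and adjusted p = 0.170 with an estimated correlation). The called members were Abca1 (-0.79 ± 0.11, adjusted p = 0.0160), Abcg1 (-0.45 ± 0.05, adjusted p = 0.0129), Srebf1 (-0.58), Mylip (-0.38) and Smpdl3a (-0.51), and 5 passed adjusted over the list alone.

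Inflammatory genes fell here too, with the NF-kB list (median log2 fold change of -0.51 over 26 tested genes, adjusted p = 5.30e-10, and adjusted p = 0.170 with an estimated correlation). Of its members 10 were called and 22 adjusted over the list alone, such as Ccl2 and Tnfaip3 (-0.35 ± 0.08, adjusted p = 0.0462), which stayed called in 1 and 0 of 9 left-out runs. Microglia markers fell (median log2 fold change of -0.36 over 31 tested genes, adjusted p = 4.13e-11, and adjusted p = 0.255 with an estimated correlation). Itgam (-0.58 ± 0.06, adjusted p = 0.0123), Mrc1 (-0.64 ± 0.09, adjusted p = 0.0160) and Cd68 (-0.37 ± 0.05, adjusted p = 0.0160) were among 11 called, with 23 lower and 1 higher (Sall1) adjusted over the list alone. Interferon genes fell (median log2 fold change of -1.03 over 36 tested genes, adjusted p = 4.64e-24, and adjusted p = 0.255 with an estimated correlation), with medians of -0.54, -1.999 and 0.18 in P11, P13 and P14. The 1 µM P13 library stood apart, with the interferon list at 1.62 against 0.16 (P11) and -0.21 (P14) at 1 µM, and the NF-kB list at 0.65 against 0.05 and -0.01 (list medians of log2 CPM, each gene less its mean over the 9 libraries). Without that library the adjusted p of the interferon list was 7.92e-10, and 4.51e-05 with the block, and that of the NF-kB list 4.80e-05 and 2.08e-12. Psmb8 (-0.80 ± 0.18, adjusted p = 0.0455) and Psmb9 (-0.74 ± 0.16, adjusted p = 0.0414) were called, which 1 and 0 of 9 left-out runs kept, with 6 adjusted over the list alone. Targets of p53 fell (median log2 fold change of -0.14 over 20 tested genes, adjusted p = 0.00336, and adjusted p = 0.255 with an estimated correlation). The called members were Cdkn1a (-0.57 ± 0.07, adjusted p = 0.0141) and Fas (-0.62 ± 0.10, adjusted p = 0.0210), and Aen also fell adjusted over the list alone. The NRF2 response fell (median log2 fold change of -0.12 over 19 tested genes, adjusted p = 0.0129, and adjusted p = 0.325 with an estimated correlation). In it Hmox1 (-0.52 ± 0.06, adjusted p = 0.0141), Slc7a11 (-0.80 ± 0.14, adjusted p = 0.0239) and Mt2A (-0.56) were lower and Ftl1 (0.34) higher, and 1 higher and 7 lower adjusted over the list alone. Without the block the p53 call ended without the 1 µM P11 library (adjusted p = 0.0822) and the NRF2 call without the 1 µM P11 (0.109) or 10 µM P14 library (0.284). With the block they were 0.00647 and 0.00514, and NRF2 ended without the 10 µM P11 (0.0621) or 10 µM P14 library (0.0831).

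Extracellular matrix genes fell (median log2 fold change of -0.48 over 34 tested genes, adjusted p = 6.23e-04, and adjusted p = 0.648 with an estimated correlation). Of them 16 were called and 24 adjusted over the list alone, such as Sparc (-0.38 ± 0.05, adjusted p = 0.0155) and Timp1 (-0.49 ± 0.10, adjusted p = 0.0374), which stayed called in 5 and 0 of 9 left-out runs. Astrocyte markers fell (median log2 fold change of -0.22 over 27 tested genes, adjusted p = 0.0129, and adjusted p = 0.534 with an estimated correlation). The called members were Clu (-0.58 ± 0.11, adjusted p = 0.0323), Gja1 (-0.51) and Slc4a4 (-0.38), and 9 fell adjusted over the list alone. Targets of Wnt, BMP and Notch fell (median log2 fold change of -0.19 over 20 tested genes, adjusted p = 0.0239, and adjusted p = 0.255 with an estimated correlation). Mitochondrially encoded genes rose (median log2 fold change of 0.34 over 13 tested genes, adjusted p = 1.09e-10, and adjusted p = 0.255 with an estimated correlation). Of them 0 were called and 11 adjusted over the list alone in the blocked fit. Nuclear oxidative phosphorylation rose (median log2 fold change of 0.07 over 59 tested genes, adjusted p = 6.62e-05, and adjusted p = 0.693 with an estimated correlation). Without the block the matrix call ended without the 1 µM P11 (adjusted p = 0.535) or 10 µM P14 library (0.396), and the astrocyte call without the 1 µM P14 (0.958) or 10 µM P11 (0.229). The Wnt call ended without the 1 µM P11 (0.0779), 1 µM P14 (0.387) or 10 µM P11 library (0.148), and the oxidative phosphorylation call without the 1 µM P14 (0.378), 10 µM P11 (0.126) or 10 µM P13 (0.0532). With the block, the oxidative phosphorylation call ended without the 10 µM P13 (0.0944) and the astrocyte call without the 10 µM P11 library (0.0966). The blocked Wnt call ended without the 1 µM P11 (0.0775), 1 µM P14 (0.218), 10 µM P11 (0.258) or 10 µM P14 library (0.170).

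A further 7 lists passed only with the block. Upward were lineage transcription factors 0.05 (adjusted p = 0.0441, adjusted p = 0.390 with an estimated correlation), with Myrf and Olig1 (0.24), and fatty acid synthesis 0.02 (adjusted p = 0.0203, adjusted p = 0.159 with an estimated correlation). Downward were cAMP-responsive genes -0.15 (adjusted p = 0.0231, adjusted p = 0.274 with an estimated correlation), with Fosl1 (-1.03) and Junb (-0.34), and the integrated stress response -0.11 (adjusted p = 0.0123, adjusted p = 0.472 with an estimated correlation), with Slc7a11 and Nupr1. Axon guidance genes -0.11 (adjusted p = 0.0203, adjusted p = 0.523 with an estimated correlation) fell too. Vascular and fibroblast markers -0.46 (adjusted p = 1.58e-05, adjusted p = 0.125 with an estimated correlation), with Col1a1 (-0.69), Col3a1 (-0.79), Dcn (-0.58) and Anpep (-0.56), also fell. Endothelial markers -0.57 (adjusted p = 0.0140, adjusted p = 0.159 with an estimated correlation) fell with Cdh5 (-0.59) and Eng (-0.57). Without the 10 µM P11 library the transcription factor (adjusted p = 0.0606), fatty acid (0.0962), cAMP (0.170), stress response (0.181) and endothelial (0.0606) calls ended. Without the 1 µM P11 library the transcription factor (0.101), fatty acid (0.115), cAMP (0.0592) and endothelial (0.0520) calls did. Without the 1 µM P13 library the transcription factor (0.235), stress response (0.0936) and axon (0.327) calls ended. Without the 10 µM P13 the transcription factor (0.190) and axon (0.223) calls ended, and without the 10 µM P14 the fatty acid call (0.0670). Under library totals without the block, lineage transcription factors passed (0.045).

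The other lists did not pass in either fit. By median log2 fold change without the block they were OPC 0.02 (adjusted p = 0.794), histamine system -0.01 (adjusted p = 0.751), MAPK feedback -0.07 (adjusted p = 0.418), cell cycle 0.05 (adjusted p = 0.751), unfolded protein response -0.04 (adjusted p = 0.884) and heat shock -0.03 (adjusted p = 0.862). They also held lysosome 0.05 (adjusted p = 0.648), hypoxia -0.08 (adjusted p = 0.115), ribosomal proteins 0.02 (adjusted p = 0.102), neuron -0.08 (adjusted p = 0.578), Schwann cell -0.00 (adjusted p = 0.631) and ependymal markers -0.43 (adjusted p = 0.231). The test direction was down for cell cycle and up for heat shock, the unfolded protein response, histamine and Schwann cell lists, against the sign of their medians. The cell cycle list, in the fit without the block, was called higher without the 10 µM P11 library (adjusted p = 1.31e-05) and lower without the 1 µM P11 (0.0411) or 10 µM P14 library (7.49e-04). Pdgfra (0.11 ± 0.05, adjusted p = 0.260), Gfap (-0.20 ± 0.05, adjusted p = 0.0654) and Mki67 (-0.15 ± 0.15, adjusted p = 0.604) did not pass. Of 33 lists, 14 passed without the block (5 up, 9 down), 21 with it (7 up, 14 down) and 0 with an estimated correlation (lowest adjusted p = 0.136 and 0.125). The 659 gene calls fell to 0 without the 1 µM P11, 1 µM P14 or 10 µM P14 library, 31 without the 1 µM P13 and 182 without the 10 µM P13, and to 420, 435 and 309 without the basal P11, P13 and P14 libraries. The calls numbered 651 without the 10 µM P11 library. Compared without all 3 basal libraries, the blocked fit called 0 genes. Without the 1 µM P11, 1 µM P14 and 10 µM P14 libraries, 2827, 2388 and 2841 genes had an unadjusted p under 0.05. Here too, runs with fewer libraries have less power.

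Both doses were set against the same 3 basal libraries, which ties their fold changes together. Across 15321 genes, the log2 fold changes at 1 µM and 10 µM had a Pearson r of 0.330, against 0.532 ± 0.0178 (SD) in 100 simulated sets with no effect and the same shared controls, and genes are not independent replicates. Their covariance was 0.0210 against 0.0227, and 61.5% of genes had the same direction against 67.4%. For genes with a mean of at least 100 reads, r was 0.196 against 0.519 and the covariance 0.00527 against 0.00824. Of the 607 genes called at 10 µM in the blocked fit, the risen had a median of 0.32 at 10 µM and 0.03 at 1 µM, and the fallen -0.49 and -0.06. These genes were selected at 10 µM against the same basal libraries, and no simulated value was made for them. Of the 607, 398 were also called between 10 µM and 1 µM, 137 higher (2.64 if independent) and 261 lower (12.1 if independent). Both of these comparisons use the same 10 µM libraries, so the counts under independence are not those for no effect. Part of any excess may come from the shared libraries. No simulated overlap was made, and 3 libraries per group cannot be split.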

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

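The combinations of the replicate block with other settings, other than leaving out single libraries for genes and an estimated correlation for lists, were chosen after seeing the data, and so were the removal of the P11 libraries, of the length trend and the edgeR fold changes for both doses. Without the block, 0 genes passed in each comparison under every other edgeR and limma setting, while DESeq2 called 59 at 10 µM, 5 at 1 µM and 58 between doses. The block gave 607, 0 and 659 genes. With the block, DESeq2 size factors gave 609 and 656 (10 µM against basal and against 1 µM), library totals 834 and 926 and DESeq2 969 and 992. Again with the block, limma on TPM gave 502 and 453, a mean of 100 reads 736 and 726, a 1.5-fold minimum 153 and 177, the 2 groups compared alone 0 and 0, and no P11 libraries 10 and 110. The last 10 genes were Zfp84 (-9.40), Lcn2, LOC100911545, Gpnmb, Abca1, Gria1, Lgals3, Lcp1, Msr1 and Gdf1 (11.9). Gdf1 had 0 reads in the basal P13 and P14 libraries and 152 and 782 at 10 µM. At 1 µM the block gave 0 genes in edgeR with all 9 libraries and 2 without the 10 µM P11 library, and DESeq2 called 11 with it. With single libraries left out, with and without the block, the counts ranged over 0 to 581 at 10 µM, 0 to 2 at 1 µM and 0 to 651 between doses. The cause was not tested, except that fewer libraries were in the fits without P11 and of 2 groups alone.

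For lists, an estimated correlation gave 0 in all 3 comparisons with and without the block, and fry gave 2, 0 and 0, or 6, 0 and 11 with the block. At 1 µM the block gave 15 lists, and 16 each with no P11 libraries, library totals or the length trend removed. Removing the length trend ended the blocked calls at 10 µM of the mitochondrially encoded (0.185) and endothelial lists (0.194). With the trend removed, 13 of the 15 blocked lists at 1 µM and 18 of the 21 between doses still passed. With no P11 libraries, 15 of the 18 blocked lists at 10 µM, 13 of the 15 at 1 µM and 14 of the 21 between doses did. Leaving out single libraries gave 10 to 22 lists at 10 µM, 6 to 16 at 1 µM and 14 to 22 between doses. The dose correlation was 0.379 with the block, 0.196 at a mean of 100 reads and 0.385 with edgeR fold changes. The cause was not tested.

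Several list tests changed direction when a library was left out, and their adjusted p ranged over 18 such runs. At 10 µM the ranges were 0.0203 to 0.894 for the integrated stress response, 1.03e-17 to 0.920 for extracellular matrix and 8.11e-08 to 0.841 for cell cycle. At 1 µM they were 1.43e-12 to 0.974 for cell cycle, 5.29e-08 to 0.999 for oxidative phosphorylation, 4.00e-07 to 0.930 for extracellular matrix, 8.53e-05 to 0.937 for myelin, 0.00166 to 0.896 for cAMP-responsive genes, 3.48e-06 to 0.583 for the unfolded protein response and 3.11e-09 to 0.604 for NF-kB. Between doses the cell cycle range was 1.31e-05 to 0.997, and with the block and no P11 libraries the list rose (0.00122). Without the block, a left-out library unbalances the P numbers between groups, so differences between P numbers enter the comparison. Myelin, cAMP-responsive, unfolded protein response and matrix lists turned lower at 1 µM without the 1 µM P11 library. These lists were higher in P11 than in P13 and P14, with medians of 0.47, 0.51, 0.37 and 1.23. Some lists also changed direction with the block, and the cause of the other changes was not tested. The main fit called 0 genes, so no named gene could lose a call against it, and over all alternatives 7304 named gene values stayed not called, 1155 passed and 95 changed sign without a call. Of the named genes called in the blocked fit, 0 of 53 at 10 µM and 0 of 58 between doses stayed called in all 9 left-out runs. Over all alternatives 2113 list values kept their side of the test, 309 passed, 211 no longer did and 214 changed sign without a call. A further 15 changed sign with a call in the main setting or in the alternative.

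Depth limits Hrh3, at 9 to 35 reads per library, and differences in Hrh4, Hdc and Hnmt were not detectable at this depth. Of the smallest simulated changes at 10 µM against basal, 0 were recovered without the block and 35.8% with it.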

Other observations

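The comparison of P numbers and the tests of cell types and of the P13 library were chosen after the results were seen. The test of gene length was added after the data were seen, but it and the count of other splits were written down before their own results were seen. With the doses held apart, 7884 of 15321 genes differed among the P numbers, and against the mean of P13 and P14 the P11 libraries had 3862 genes higher and 3889 lower. These tests take the libraries of a number as its replicates. Their p-values use the spread left within numbers and do not measure the spread between numbers. Matrix genes were higher in P11, with a median of 1.23 (adjusted p = 2.76e-33, and adjusted p = 0.0696 with an estimated correlation), 28 higher and 2 lower of 34. So were vascular and fibroblast markers, with a median of 1.57 (adjusted p = 6.07e-10, and adjusted p = 0.0696 with an estimated correlation), 13 higher and 2 lower of 17. The collagen genes Col1a1 (2.25 ± 0.09, adjusted p = 1.27e-06) and Col3a1 (2.38 ± 0.09, adjusted p = 1.15e-06) and the fibronectin gene Fn1 (2.68 ± 0.12, adjusted p = 1.79e-06) were among the highest. Late myelin genes were higher too, with Mobp (2.35 ± 0.09, adjusted p = 1.11e-06), Mog (1.81 ± 0.08, adjusted p = 1.57e-06) and Opalin (1.81 ± 0.09, adjusted p = 3.16e-06), while Mbp (-0.08 ± 0.06, adjusted p = 0.277) did not pass. Schwann cell markers moved with them, with a median of 1.04 (adjusted p = 3.48e-04, and adjusted p = 0.0833 with an estimated correlation), 5 higher and 1 lower of 9, and endothelial markers had a median of 0.84 (adjusted p = 0.0249, and adjusted p = 0.228 with an estimated correlation), 5 higher and 3 lower of 9. The myelin list had a median of 0.47 (adjusted p = 6.67e-17, and adjusted p = 0.0696 with an estimated correlation), 29 higher and 3 lower of 39.

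The unfolded protein response was higher in P11, with a median of 0.37 (adjusted p = 7.07e-08, and adjusted p = 0.132 with an estimated correlation), 19 higher and 0 lower of 21, such as the chaperone Hspa5 (0.50 ± 0.04, adjusted p = 1.94e-05). The integrated stress response had a median of 0.51 (adjusted p = 5.65e-06, and adjusted p = 0.235 with an estimated correlation), 19 higher and 2 lower of 26. Heat shock genes had a median of 0.25 (adjusted p = 0.00648, and adjusted p = 0.235 with an estimated correlation), 10 higher and 0 lower of 16, and hypoxia genes a median of 0.26 (adjusted p = 1.99e-04, and adjusted p = 0.373 with an estimated correlation), 18 higher and 4 lower of 32. The NRF2 response did not pass, with a median of 0.06 (adjusted p = 0.641, and adjusted p = 0.914 with an estimated correlation), 6 higher and 3 lower of 19. Genes responsive to cAMP had a median of 0.51 (adjusted p = 1.74e-05, and adjusted p = 0.0833 with an estimated correlation), 21 higher and 3 lower of 31, with Fos (0.90 ± 0.09, adjusted p = 8.73e-05). Cell cycle genes were lower, with a median of -0.75 (adjusted p = 1.89e-06, and adjusted p = 0.575 with an estimated correlation), 0 higher and 25 lower of 38, such as Top2a (-0.85 ± 0.13, adjusted p = 9.01e-04) and Mki67 (-0.52 ± 0.13, adjusted p = 0.0108). Neuron markers were lower with a median of -0.57 (adjusted p = 1.12e-09, and adjusted p = 0.0696 with an estimated correlation), 5 higher and 18 lower of 25, such as the tubulin gene Tubb3 (-0.82 ± 0.08, adjusted p = 6.58e-05). Microglia markers were lower with a median of -0.33 (adjusted p = 0.00176, and adjusted p = 0.564 with an estimated correlation), 3 higher and 20 lower of 31. These values come from the fit with the P number as a block, so their p-values too use the spread within numbers.

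Cholesterol synthesis and myelin genes rose together at 10 µM. More cells of the whole lineage would raise precursor and myelin markers alike, but the myelin median exceeded the OPC median by 0.22 ± 0.04 (SD over 3 P numbers). That goes against a uniform rise of the lineage as the only cause. A larger lineage share beside other changes was not excluded, since astrocyte and microglia marker lists fell. Of the precursor genes, Olig1 and Olig2 were called higher, while Pdgfra and Cspg4 did not pass. Another list also holds 6 of the myelin, 5 of the OPC and 0 of the cholesterol genes. Over all genes, the fold change at 10 µM was lower for longer genes (Spearman -0.277). Medians with this trend removed were made for the cholesterol and myelin lists only. For these lists gene length as the cause is argued against, since removing its trend moved the cholesterol median from 0.40 to 0.45 and the myelin median from 0.26 to 0.32. A larger share of mature oligodendrocytes may explain the pattern and stays open, as 2 tests of it differed. The first, on the whole lists, put the cholesterol median above the myelin median by 0.145, 0.234 and 0.0719 in P11, P13 and P14 (mean 0.150 ± 0.081, SD), which goes against it. After that result was seen, the test was changed to 7 myelin genes fixed before the data were examined, and the cholesterol median less their mean was -0.00153 ± 0.078 (SD), which does not. An effect of bavisant on these genes in each cell stays open too.

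Inflammatory genes fell at 10 µM. Fewer microglia in the cultures would lower microglia markers at least as much, but the NF-kB median lay below the microglia median by 0.19, 0.07 and 0.17 in P11, P13 and P14 (mean difference -0.15 ± 0.06, SD), with 0 NF-kB genes and 1 microglia gene also in another list. The microglia medians were -0.0046, -0.29 and -0.25 in the same order. A change in a subset of macrophages may explain the fall of inflammatory genes and stays open, as does lower inflammatory signalling with bavisant.

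Interferon genes were high in the 1 µM P13 library. There the interferon list exceeded the microglia list by 1.58, each measured against the other P13 libraries (1.82 and 0.24), against 0.17 and -0.40 in P11 and P14, which argues against more microglia, and 0 interferon genes are in another list. A mislabelled number is argued against by its lowest correlation with its own number, 0.319, above the highest with another, 0.0944. An interferon response in that culture may be the source and was not tested, and the 1 library cannot separate it from the dose.

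Other splits of the libraries are too few for a share under 0.05 (10 without the block, 4 that part every pair with it). Without the block the real count of genes was 0 in each comparison (highest other 0), which 10 of 10 splits reach by construction, so these counts say nothing about chance. As many lists came from 3 splits at 10 µM (real 14, highest other 16), 8 at 1 µM (8 and 18) and 6 between doses (14 and 18). With the block, as many genes came from 1 of 4 splits at 10 µM (real 607, highest other 0) and 1 between doses (659 and 0), while all 4 reach the real 0 at 1 µM by construction (highest other 0), and as many lists from 1 (18 and 13), 2 (15 and 15) and 1 (21 and 15).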
